A study of Mus musculus with 6 samples.

How the data were processed

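Total RNA from laser-captured crypt base epithelium of the mouse ileum was hybridised to 6 one-colour arrays, 3 from WT and 3 from Nod2-/- mice, as the labels give them. The tissue was fixed in methacarn, an alcohol-based fixative, before paraffin embedding, and 100 ng of RNA was labelled, per the labels' protocols. Per the labels' design text, the crypt base was chosen by its place in the tissue to enrich for Paneth cells. The number of arrays limits the precision. The laser captures are treated as 6 samples, because the labels tie no capture to an animal.

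The value table holds a deposited intensity for each of 28853 probe sets and 6 arrays, summarised by RMA per the submitters' processing notes. RMA corrects the background, normalizes arrays to the same distribution by quantiles and summarises probes. Its software and settings are not given in the sources used here. The deposited intensities are on a linear scale, between 18.8 and 12280, so log2 was taken before any test. A second deposited table holds 3.65% of the probe sets, with gene symbols and positions, and per the file headers it uses the MoGene 1.0 ST array, annotation release 31 and mouse build mm9. Its intensity columns equal the value table in all of them (relative tolerance 0.001). Its further columns are a ratio to the WT median and a log2 value minus the WT median, per the file headers, and both were recomputed and equal in all of them. The authors' columns of folds are an absolute fold and a signed fold score, which is negative where Nod2-/- is lower. The authors' log2 fold was equal to the difference of mean log2 values in all 962 probe sets that have one. The authors' p-value columns come from an unpaired test without adjustment, per the file headers, and recomputation on log2 values gave the same in 287 of 287 and on linear values in all that the table holds (relative tolerance 0.01). The table is therefore the union of a log2 difference of at least 0.41 in either direction and of p of 0.05 or less with a log2 difference of at least 0.32, the logs of the fold thresholds in the headers. It was selected on the outcome, so its contents are not a sample of all genes, and no value of the authors' comparison columns is printed as a result.

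Of its probe sets, 855 have 1 symbol, 104 have several and 94 have none. The 855 stand for 744 genes. Symbols were brought up to date by Entrez number through the RefSeq genes of GRCm38.p6, in which 800 matched and 116 changed name. Where a gene had several probe sets in the table, which held for 38 genes, the one with the highest mean over all arrays stands for the gene in the lists, and 12 of these genes had probe sets of both directions. All other probe sets are unnamed here. Coordinates are those of the authors' table in mm9, and RefSeq was used only for names and for which genes neighbour each other.

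Groups came from the genotype labels. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on log2 intensities of all 28853 probe sets, with genotype as the only term, no filter on low values and Benjamini-Hochberg adjustment with a threshold of 0.05. The prior had 1.74 degrees of freedom beside 4 residual ones. The fit was tested on simulated data with the spread of these arrays, in which 36 of 50 probe sets changed 2-fold, 45 of 50 changed 4-fold, 49 of 50 changed 8-fold and 49 of 50 changed 16-fold were called among 28853, with 15 false calls. The changed probe sets were drawn at random with independent errors, and the median residual SD of the real data was 0.12 (log2). The shares called therefore cannot be carried over to probe sets that vary more, such as Retnlb, with a standard error of 0.76. Per group, values are means ± SD of 3 log2 intensities, and folds are 2 to the power of the difference of means. Python 3.11.15 with scipy 1.17.1 was used for the lists.

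The rule for named genes, the gene lists, the test and most alternatives were chosen before the data were examined. The rule takes Nod2, then the genes with 1 symbol past the adjusted threshold whose arrays do not overlap between genotypes, up to 10 in each direction by size. Where fewer pass, places are filled by the smallest unadjusted p among genes with non-overlapping arrays and a fold of at least 1.5. It adds 23 genes whatever their values and up to 4 members of each list that passes its test. The planned test of lists, camera with a preset correlation of 0.01, needs names for all probe sets and was not run. In its place, chosen after the table was seen, a one-sided binomial test compared the number of list members in the table with the share of all probe sets that are in it (3.65%), and, as the stricter form that is reported, with the highest share in any of 10 equal bands of probe sets by mean intensity (8.28%). Adjustment was over the 25 lists of known size. Members not on the array count as absent, and genes of a list are treated as independent, so these p-values describe membership and do not replace camera. Of 2000 random lists of probe sets, tested against the share of 3.65%, 0.6% had p under 0.05. These were independent draws, so they do not test the stricter form or lists of genes that change together. A two-sided Fisher's exact test compared directions with those of the 744 genes, of which 447 were higher and 297 lower. The count adjusted over the list alone treats members outside the table as not passing and counts them in the adjustment. All members in the table are named, which goes beyond the rule and was decided after their values were seen, as were the probe sets at least 4-fold apart.

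Numbers in the form of a date in the column names of the authors' table gave 2 possible batches, called dates here, each with both genotypes. What they date is not stated. Alternatives were the replicate number as a block, renewed quantile normalization, centring on the array median, filters at the 25th percentile and the median of mean intensity, a trended and robust prior, array weights, the authors' unpaired test, and leaving out each array. The date as a block and the date of replicates 2 and 3 alone were added after the data were seen. Renewed normalization and centring left the median log2 difference of all probe sets between -0.007 and -0.004.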

Results

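Gene expression was measured in epithelium cut by laser from the base of ileal crypts, the place where Paneth cells sit between the stem cells and release antimicrobial proteins into the gut lumen. The mice were 8 weeks old, on the C57BL/6J background, and either wild type (WT) or without a working Nod2 gene (Nod2-/-). Nod2 is an intracellular receptor for fragments of bacterial cell walls. There were 6 Affymetrix MoGene 1.0 ST arrays, 3 per genotype, each made from 100 ng of total RNA. The median intensity per array lay between 34.5 and 35.4, and the correlation of log2 values between any pair of arrays, across probe sets, lay between 0.971 and 0.987. Probe sets are not independent replicates, so this correlation describes the arrays and tests nothing. With 3 arrays per group, the number of arrays limits the precision. The labels do not say that the arrays come from separate mice, so the p-values measure the spread between these samples only, which may be partly technical.

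The comparison asked which transcripts of the crypt base differed between Nod2-/- and WT. The probe set shared by Sprr2a1, Sprr2a2 and Sprr2a3, which encode small proline-rich proteins of epithelia, averaged 11.08 ± 0.55 (log2 intensity, SD, n = 3) in Nod2-/- and 6.71 ± 0.40 in WT, the highest fold of all, 20.7. Retnlb, a secreted antibacterial protein of goblet cells, was 13.3-fold higher in Nod2-/- (8.38-fold without WT replicate 1, 20.4-fold without WT replicate 2), and Pla2g4c, a phospholipase, was 11.8-fold higher (6.97-fold without Nod2-/- replicate 2, 17.8-fold without Nod2-/- replicate 3). The 4 probe sets of the gasdermin C family (3.53-fold to 7.52-fold), Defb1 (a beta-defensin, 5.99-fold), Mptx1 (a mucosal pentraxin, 4.53-fold) and Clca1 (a secreted goblet cell protein, 4.09-fold) were also higher.

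None of these differences passed the test. With limma over 28853 probe sets, 0 had an adjusted p under 0.05, and the lowest adjusted p was 0.183. Without adjustment, 1106 probe sets had p under 0.05, of which 578 were higher and 528 lower in Nod2-/-. At least a 1.5-fold difference was found for 146 of these, 94 higher and 52 lower. The authors' unpaired test, recomputed from the same values, gave 1043 probe sets at p of 0.05 or less and 0 after Benjamini-Hochberg adjustment, where its lowest adjusted p was 0.196. The Sprr2a probe sets alone passed under other settings of limma. With probe sets below the median intensity left out, 3 passed, with a lowest adjusted p of 0.024, and 3 passed with a trended and robust prior, with a lowest adjusted p of 0.006. Without Nod2-/- replicate 1, 2 passed. The column names of the authors' table carry one number in the form of a date for replicate 1 of both genotypes and another for replicates 2 and 3. What they date is not stated, and they were taken as possible batches, called dates here, each with both genotypes. With the date as a block in limma the count was 0 and the lowest adjusted p 0.432, and within the date of replicates 2 and 3 the count was 0 and the lowest adjusted p 0.184. The other date held 1 array per genotype and gave differences without a test.

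In all, 12 probe sets differed at least 4-fold, 11 of them higher and 1 lower in Nod2-/-. They were singled out after their values were seen. In each of the 12 the 3 arrays of one genotype did not overlap with the 3 of the other, which chance gives for 10% of probe sets not chosen by their fold, so for these it is no further evidence. The probe set of the Sprr2a genes (chromosome 3, 92019757 to 92026413, mm9) had a log2 difference of 4.37 with a standard error of 0.33 (limma, adjusted p = 0.183). A further pair of probe sets, shared by Sprr2a1 and Sprr2a3 and overlapping on the genome, each had a log2 difference of 3.18 (limma, adjusted p = 0.235). These genes are near copies, so their signals cannot be separated. Retnlb (chromosome 16, 48816969 to 48819017) averaged 9.77 ± 0.91 in Nod2-/- and 6.04 ± 1.29 in WT, with log2 differences of 6.05 on the date of replicate 1 and 2.57 on the other date. Pla2g4c (chromosome 7, 13911016 to 13945292) averaged 8.58 ± 1.39 against 5.02 ± 0.27, with differences of 3.44 and 3.63 within the dates. Its WT mean lay below the median of every array (5.11 to 5.15), and signal over background was not analysed, so its fold may be too low. The probe set of Gsdmc2 alone (chromosome 15, 63655901 to 63676731) averaged 9.16 ± 0.71 against 6.36 ± 1.36 (log2 difference 2.80, and 2.02 without WT replicate 1), and those shared with Gsdmc3 or Gsdmc4 lay beside it. Of 4 gasdermin C probe sets, 1 was under 4-fold. Clca1 (chromosome 3, 144667501 to 144695736, named Clca3 in the authors' table) averaged 10.23 ± 0.21 against 8.20 ± 0.89. The median log2 difference of the 11 was 3.78 on the date of replicate 1 and 2.42 on the other date. The probe set that was lower had no gene symbol (chromosome 19, 3134221 to 3143065) and averaged 5.40 ± 0.34 in Nod2-/- and 7.40 ± 1.05 in WT.

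**Figure D1:**
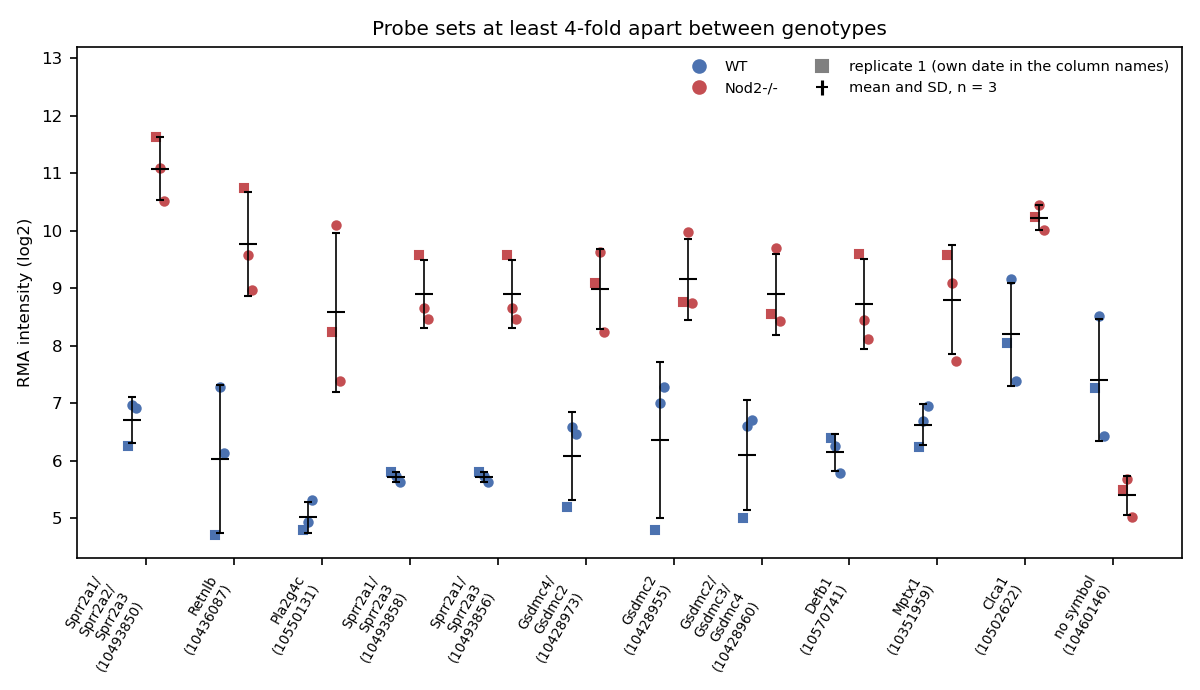
RMA intensity (log2, vertical axis) on each of the 6 arrays for the 12 probe sets at least 4-fold apart, with the gene symbols and probe set numbers on the horizontal axis. Points are arrays (squares, replicate 1), and bars give the mean and SD of 3 arrays. In 11 probe sets every Nod2-/- array lies above every WT array, and in the one without a symbol every Nod2-/- array lies below.

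The genes chosen by the rule fixed beforehand were those with the smallest unadjusted p among genes at least 1.5-fold apart whose arrays did not overlap, 10 in each direction, and none of the 20 passed limma's adjusted threshold. Among the higher genes, Wfikkn2, a secreted protease inhibitor domain protein (chromosome 11, 94097276 to 94097707), averaged 7.57 ± 0.12 in Nod2-/- and 6.41 ± 0.10 in WT, which is 2.23-fold (limma, adjusted p = 0.183). Fut2, the enzyme that fucosylates the gut surface (chromosome 7, 52903965 to 52921764), was 2.10-fold higher, at 6.82 ± 0.18 against 5.75 ± 0.31. Rnase1, a secreted ribonuclease (chromosome 14, 51764677 to 51766442), was 2.29-fold higher, at 10.17 ± 0.21 against 8.97 ± 0.27. Defb1 (chromosome 8, 22887071 to 22905657) averaged 8.73 ± 0.78 against 6.15 ± 0.32. Ms4a7, Pdss1, Pde2a and C330007P06Rik were between 1.54-fold and 1.81-fold higher, and Pla2g4c and Retnlb completed the 10.

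Among the lower genes, Prdx2, a peroxidase of the cytosol (chromosome 8, 87493521 to 87498707), averaged 6.31 ± 0.04 in Nod2-/- and 6.93 ± 0.01 in WT, a 1.54-fold difference (limma, adjusted p = 0.183). Gm4964, as the authors' table names an immunoglobulin kappa variable segment (chromosome 6, 67560201 to 67560536), was 3.06-fold lower, at 4.95 ± 0.10 against 6.56 ± 0.67. Eef1akmt1, a methyltransferase of elongation factor 1A (named N6amt2 there), was 1.87-fold lower, and Crim1, a transmembrane protein that binds bone morphogenetic proteins, was 1.65-fold lower. Ube2s, Proser3, Samd5, Ndufaf1, Zfp141 and Api5 were between 1.5-fold and 1.58-fold lower. Apart from Wfikkn2, Prdx2 and Ms4a7 (adjusted p = 0.748), the adjusted p of these 20 genes with limma was 1.00.

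The authors' table gives gene names for part of the array, and it holds every probe set with a log2 difference of at least 0.41 in either direction (962) or with p of 0.05 or less in their unpaired test and a log2 difference of at least 0.32 (287). Only the probe sets in this table carry gene names here, so a gene without a place in it was either below those thresholds or not measured under its symbol. As the table was selected on the difference, means and medians of the listed genes in it describe these genes and do not test the lists. Nod2 has no place in it, and the level of the targeted gene was not analysed here and does not check the genotype labels. Of the other 23 genes fixed for naming whatever their values, 6 are in it. Reg3b and Reg3g, antibacterial lectins, were 3.68-fold and 1.94-fold higher in Nod2-/-, and 1.68-fold and 1.23-fold higher without WT replicate 1, while Reg3b was 6.73-fold higher without WT replicate 2. Chga, an enteroendocrine granule protein, and Dclk1, a tuft cell kinase, were 1.35-fold and 1.45-fold higher. Lgr5, a stem cell receptor, and Fabp6, the ileal bile acid binding protein, were 1.37-fold and 1.71-fold lower, and without WT replicate 1 Fabp6 was 1.07-fold lower. The limma adjusted p of all 6 was 1.00. Lyz1, Mmp7, Ang4, Itln1, Defa24, Ripk2, Atg16l1, Nfkbia, Xbp1, Olfm4, Mki67, Muc2, Fabp1, Ptprc, Igkc, Col1a1 and Acta2 have no place in it.

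Among the lists fixed beforehand, markers of tuft cells, the chemosensory cells of the gut lining, had the most members in the table. Of 24 tuft cell genes, 10 were in it where 1.99 were expected at the highest background share, and all 10 were higher in Nod2-/-, with a median log2 difference of 0.61. They were Rgs13 (2.74-fold), Spib (1.96-fold), Alox5ap (1.93-fold), Sh2d6 (1.89-fold), Pou2f3 (1.56-fold), Trpm5 (1.49-fold), Alox5 (1.47-fold), Avil (1.46-fold), Dclk1 (1.45-fold) and Ptgs1 (1.42-fold). Spib is also expressed by Paneth cells. The binomial test gave an adjusted p of 2.5e-04 over 25 lists against that share, the highest in the table of any of 10 bands of probe sets by mean intensity (8.28%). It counts the genes of a list as independent, although they can change together. This p-value and those of the lists below therefore describe membership in the table and do not test genotype between arrays. The mean log2 value of the 10 genes was 6.09 ± 0.45 (SD, n = 3) in Nod2-/- and 5.32 ± 0.06 in WT. For Nod2-/- replicates 1, 2 and 3 it was 6.42, 6.26 and 5.57. An exact two-sided permutation of the 6 arrays gave p = 0.1 for this mean, the smallest possible with 3 against 3. The 10 genes are in the table because of their difference, so this p-value is not independent of their selection. In 5 of the 10 genes the arrays of the genotypes did not overlap. With 1 array left out the median lay between 0.52 and 0.82. The WT means of Alox5 (4.75), Dclk1 (5.01) and Spib (5.06) lay below the median of every array (5.11 to 5.15), and signal over background was not analysed. All 10 were higher on both dates, with medians of 0.92 and 0.50. The share of higher genes was not above that of the whole table (447 of 744 genes) after adjustment (Fisher's exact test, p = 0.007, adjusted p = 0.114). With limma 0 passed over all probe sets and 0 adjusted over the list alone.

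Products of Paneth cells other than defensins had 7 of 30 genes in the table, all higher in Nod2-/-, with a median log2 difference of 0.96 (binomial adjusted p = 0.049). They were Mptx1, Reg3b, Reg4 (2.44-fold), Reg3g, Pnliprp2 (1.70-fold), Kit (1.49-fold) and Clps (1.37-fold). Their mean log2 value was 10.9 ± 0.41 in Nod2-/- and 9.78 ± 0.25 in WT, and the medians within the dates were 1.04 and 0.86. Without WT replicate 1 the median was 0.75. In 3 of the 7 genes the arrays of the genotypes did not overlap, and with limma 0 passed adjusted over the list alone. Reg3b and Reg3g are counted again among the microbiota-responsive genes below, so the 2 lists are not separate results. No probe set named for an alpha-defensin is in the table. It does hold 6 probe sets without a symbol within 1 Mb before Defb1 (chromosome 8, 22179935 to 22687891, mm9), a stretch picked after the values were seen, where 11 of the 12 protein-coding genes next to Defb1 in the RefSeq annotation of GRCm38.p6 are alpha-defensins. On average all 6 were lower in Nod2-/-, with log2 differences between -1.62 and -0.50, but in 5 of them the arrays of the genotypes overlapped. In those starting at 22358673, 22448851 and 22687122, each Nod2-/- array lay below each WT array of its own date. For the last, the values were 7.83 against 8.30 on the date of replicate 1. On the other date they were 6.58 and 6.08 against 6.99 and 7.36. This look within dates was also made after the values were seen. In the probe set at -1.62, WT replicate 2 (4.52) lay among the Nod2-/- arrays (4.44 to 4.62), and without WT replicate 3 the difference was -1.06. The smallest pair of differences rested on WT replicate 3, without which both were -0.14. Which genes these probe sets measure is not known here.

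Microbiota-responsive genes of the epithelium had 7 of 23 in the table, 6 of them higher, with a median of 0.96 (binomial adjusted p = 0.017). Besides Retnlb, Fut2, Reg3b and Reg3g these were Duox2 (1.61-fold) and its partner Duoxa2 (1.39-fold), and Zg16, a goblet cell lectin, was 3.89-fold lower (2.57-fold without WT replicate 1, 7.53-fold without WT replicate 3). The 3 Sprr2a probe sets also belong to this list and were not counted, as they are shared between genes. Of its members 2 passed adjusted over the list alone and 0 over all probe sets with limma. The medians within the dates were 1.31 and 0.61. WT replicate 1 was the lowest WT array for all 6 higher genes, Retnlb included, and without it the median was 0.37. Goblet cell markers had 6 of 24 in the table (binomial adjusted p = 0.049), 4 higher and 2 lower. Retnlb, Clca1, Ccl9 (1.76-fold) and Spdef, a transcription factor of goblet cells (1.39-fold), were higher, and Zg16 and Tff3 (1.36-fold) were lower. In both lower genes the arrays of the genotypes overlapped. For Zg16, WT replicate 3 (4.92) lay among the Nod2-/- arrays (4.79 to 5.01). The log2 difference of Tff3 was -0.44, and -0.13 without WT replicate 1. Retnlb and Zg16 are also counted among the microbiota-responsive genes. The median of the 6 goblet markers was 0.65, and 0.90 and 0.52 within the dates. All 4 higher ones passed adjusted over the list alone and 0 over all probe sets with limma.

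Crypt stem cell markers went the other way. Of 30 genes, 7 were in the table (binomial adjusted p = 0.049), and 6 of them were lower in Nod2-/-. Slc14a1 was 1.85-fold lower, Esrrg 1.77-fold, Rnf32 1.67-fold, Rgmb 1.40-fold, Lgr5 1.37-fold and Tnfrsf19 1.34-fold, while Prom1 was 1.37-fold higher. The median was -0.49, and -0.49 and -0.52 within the dates. The mean log2 value was 6.75 ± 0.30 against 7.23 ± 0.22 (exact two-sided permutation of the arrays, p = 0.2). The share of lower genes did not pass (Fisher's exact test, p = 0.018, adjusted p = 0.139). Lgr5 was 0.014 higher on the log2 scale without Nod2-/- replicate 2. Cell cycle genes had 2 of 40 in the table, Cdk1 higher and Bub1 lower. Enterocyte markers had 5 of 51, of which Fabp6, Otc, Anpep and Fabp2 were lower and Slc51b was higher. Enteroendocrine markers had 5 of 27, of which Tac1 (2.45-fold), Cck and Chga were higher. Ghrl was higher over all arrays but lower without Nod2-/- replicate 1 (-0.62 on the log2 scale), and Sst was lower over all arrays but higher on the date of replicate 1 (1.86, against -2.19 on the other date).

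**Figure D2:**
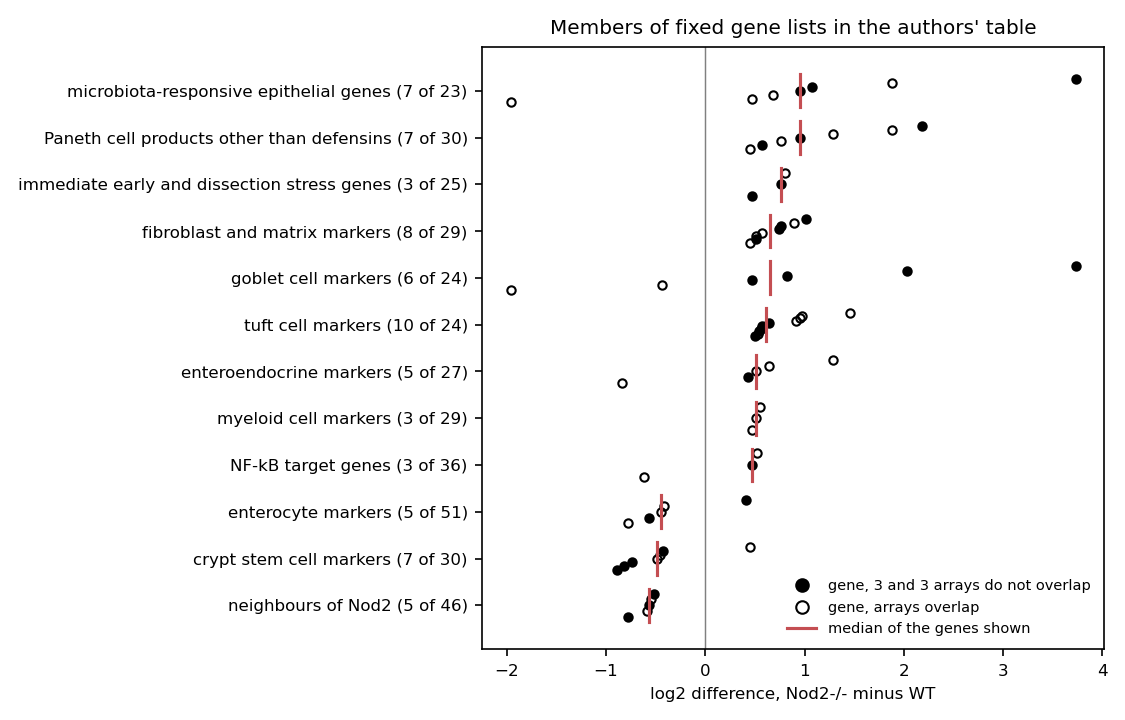
Log2 difference between Nod2-/- and WT (horizontal axis) of each gene of a list fixed beforehand that is in the authors' table, for the lists with at least 3 such genes (vertical axis, with the number in the table and the size of the list). Filled points are genes whose 3 Nod2-/- arrays do not overlap with the 3 WT arrays, and red lines are medians. All 10 tuft cell genes lie to the right of 0, and 6 of the 7 stem cell genes lie to the left.

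Markers of cells that lie around the crypt were also in the table. Fibroblast and matrix genes had 8 of 29, all higher in Nod2-/-, with a median of 0.65 (binomial adjusted p = 0.017). Fn1 was 2.02-fold, Igfbp5 1.86-fold, Bgn 1.69-fold and Lum 1.67-fold higher, and Mgp, Sparc, Ccl11 and Col3a1 lay between 1.36-fold and 1.48-fold. Their mean log2 value was 8.28 ± 0.35 against 7.60 ± 0.42. The medians within the dates were 0.88 and 0.52, and without WT replicate 1 the median was 0.36. Ccl11 was lower in Nod2-/- on the date of replicate 1 (-0.35 on the log2 scale). Myeloid markers had 3 of 29 in the table, all higher (Fcer1g, C1qc and Tyrobp), and without WT replicate 1 their median was 0.0012. Smooth muscle markers had Actg2 and Cald1 of 21, and endothelial markers Emcn of 22, all higher. The class II genes Cd74 and H2-Aa and the lymphocyte gene Cd52 were higher over all arrays and lower without WT replicate 1. Of the B and plasma cell list only Ighm was counted in the table, 1.91-fold lower, and 1.26-fold lower without WT replicate 2. Counted by name after the values were seen, 17 probe sets in the table belong to immunoglobulin genes, Ighm and Gm4964 included, 3 of them higher and 14 lower. Of the erythroid genes only Hbb-b1 and Hbb-b2 were in the table, in 2 shared probe sets that were 1.44-fold and 1.54-fold higher over all arrays and 1.49-fold and 1.22-fold lower without Nod2-/- replicate 2. Apart from the fibroblast genes, these lists did not pass the binomial test, nor did the cell cycle, enterocyte and enteroendocrine lists.

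Of 34 genes of Nod2 signalling, 0 were in the table. Of 36 NF-kB targets, Bcl3 and Junb were higher and Ccl28 was lower. Of 44 interferon-stimulated genes, Ifi27l2a and Ifit3 were higher. Dnajb9 was the only one of 33 genes of the unfolded protein response with a probe set of its own, 1.34-fold lower, and a probe set shared by Ddit3 and Mars was 1.49-fold higher. Atg12, 1.28-fold lower, was the only one of 36 autophagy genes. Among the lists for sample handling, the immediate early genes Dusp1, Socs3 and Junb were higher (3 of 25 in the table, of which 1, Junb, passed limma adjusted over the list alone), and the clock genes Per1 and Nfil3 were higher (2 of 20). No probe set in the table was named for a mitochondrially encoded gene, and none for a ribosomal protein gene alone. A probe set shared by Snord68 and Rpl13 was higher and one shared by Snord34 and Rpl13a lower. The table does hold probe sets without a symbol on the mitochondrial chromosome, some of them higher in Nod2-/-. Which genes they measure is not known here, so the count by name cannot show whether mitochondrial transcripts differed. None of these pathway and handling lists passed the binomial test.

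Genes near the targeted locus were listed beforehand because they travel with it in crosses. Of 46 neighbours of Nod2, 5 were in the table and all 5 were lower in Nod2-/-. They were Nkd1, an inhibitor of Wnt signalling (chromosome 8, 91045253 to 91116950, 1.72-fold), Tox3 (92770939 to 92872431, 1.5-fold), Orc6 (87823690 to 87831970, 1.48-fold), Fto (93837431 to 94192336, 1.46-fold) and Gpt2 (88016484 to 88051459, 1.43-fold). Their median log2 difference was -0.57, and -0.44 and -0.66 within the dates. Their mean log2 value was 5.96 ± 0.20 against 6.56 ± 0.18. Neither their number (binomial adjusted p = 0.858) nor their direction (Fisher's exact test, p = 0.01, adjusted p = 0.114) passed.

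**Figure D3:**
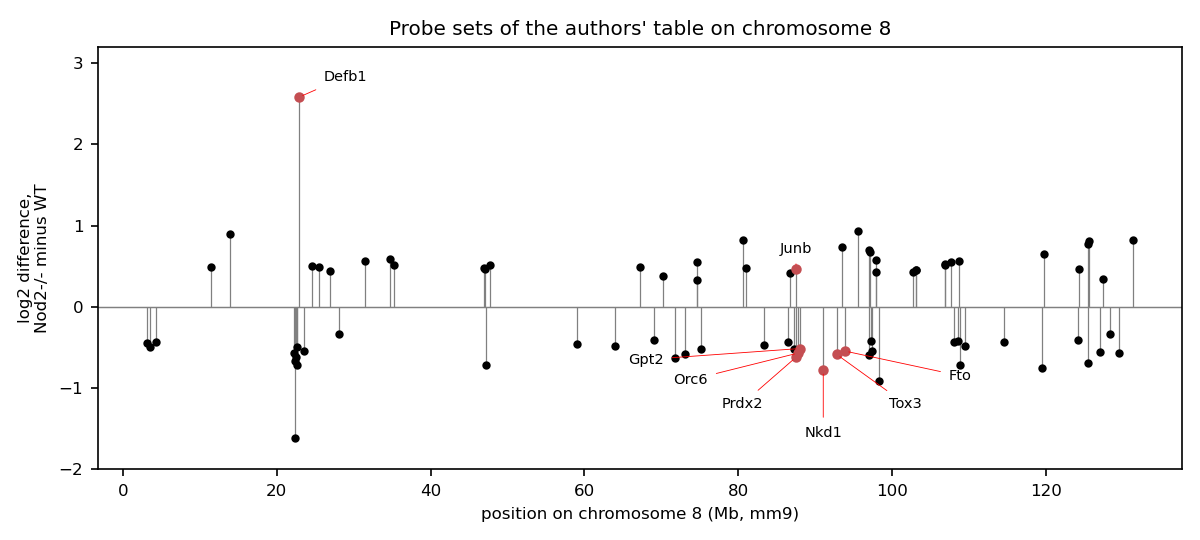
Log2 difference between Nod2-/- and WT (vertical axis) of the probe sets of the authors' table on chromosome 8, by position in Mb (mm9, horizontal axis). Red points mark Defb1 and Junb, above 0, and Prdx2 and the 5 listed neighbours of Nod2, below 0.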

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

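The date settings were added after the data were seen, and the other settings were planned. Of 1933 pairs of a setting with a named probe set, or with the count at the authors' thresholds, 1922 kept the direction and 11 did not. The replicate and date blocks, the filters, the trended and robust prior and the unpaired test leave each log2 difference unchanged by construction. Their pairs could not turn, so this agreement was partly fixed in advance. The count at adjusted p under 0.05, 0 with limma as planned, was 3 with the filter at the median, 3 with the trended and robust prior and 0 to 2 with 1 array left out. All these calls were Sprr2a probe sets, and the filter tests fewer probe sets. The count at unadjusted p under 0.05 was 529 with the filter at the median, which tests 14427 probe sets, against 1106. The count with a fold of at least 1.5 besides (146) was 94 with the authors' unpaired test, 228 within the date of replicates 2 and 3, and 164 to 267 with 1 array left out. The count of probe sets with a log2 difference of at least 0.41 (962) was 1036 to 1533 with 1 array left out. With the replicate number as a block, the adjusted count was 0 and the lowest adjusted p 0.969, and 1398 probe sets had unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.20, -0.02 and 0.06. The highest was that of replicate 1, whose 2 arrays share a date. Deviations from a mean of 3 arrays depend on each other, so these values cannot show whether the numbers pair the arrays. Medians of lists with 1 array left out were 0.37 to 1.23 for microbiota-responsive genes, -0.78 to -0.43 for stem cell markers and 0.91 to 1.27 for the type 2 genes chosen after the data were seen, which had 1.21 within the date of replicates 2 and 3 against 1.03.

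With 1 array left out, the log2 difference ranged from -0.78 to 0.014 (highest without Nod2-/- replicate 2) for Lgr5, from -0.23 to 1.14 for Cd74, -0.36 to 0.93 for H2-Aa, -0.26 to 1.06 for Cd52 and -0.070 to 0.83 for Tyrobp (each lowest without WT replicate 1), -0.62 to 1.12 for Ghrl (lowest without Nod2-/- replicate 1) and -0.58 to 1.09 for one probe set of Hbb-b1 and Hbb-b2 (lowest without Nod2-/- replicate 2). The fold of 16 named genes moved by over 1.5 times with 1 array left out. Besides these, log2 differences without WT replicate 1 were 3.07 for Retnlb, 2.02 for Gsdmc2, 0.75 for Reg3b, 0.30 for Reg3g, -0.095 for Fabp6, -1.36 for Zg16 and -1.90 for Sst. Without WT replicate 2 those of Retnlb, Reg3b and Ighm were 4.35, 2.75 and -0.33, and without WT replicate 3 that of Zg16 was -2.91. Without Nod2-/- replicate 2 that of Pla2g4c was 2.80, and without Nod2-/- replicate 3 those of Pla2g4c, Mcpt1 and Mcpt2 were 4.16, 0.54 and 0.13. Within the date of replicates 2 and 3, Cd74 (-0.53), H2-Aa (-0.45), Ghrl (-0.45) and Cd52 (-0.19) turned. Beyond fewer samples, the cause was not tested. Camera with either correlation, fry, 1 probe set per gene, the mean of the probe sets of a gene and the Nod2 level were not run, since names cover only the authors' table, and that table repeats the same values. Signal over background was not analysed here.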

Other observations

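All tests of explanations here were chosen after the results they bear on were seen. Beyond the lists fixed beforehand, several further genes chosen after their values were seen were higher in Nod2-/-. Serpina3n, a secreted protease inhibitor, was 3.16-fold higher, S100a6, a calcium-binding protein, 2.35-fold, and the mast cell proteases Mcpt1 and Mcpt2 2.53-fold and 1.98-fold, which without Nod2-/- replicate 3 were 1.46-fold and 1.09-fold. Reg1 (2.06-fold), Pnliprp1 (2.50-fold) and Fam3b (2.04-fold) were also higher, as were Rgs5 (2.51-fold), a marker of pericytes, and Hmcn1 (2.27-fold), a matrix protein. The limma adjusted p of each was 1.00. A list of 33 genes known to follow type 2 cytokines or worm infection in the gut, written after the table was seen, had 12 in it, all 12 higher, and its mean log2 value was 7.18 ± 0.12 (SD, n = 3) in Nod2-/- and 5.62 ± 0.26 in WT. This list was built around genes already seen, so its direction is not independent evidence.

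The first pattern is the set of 11 probe sets at least 4-fold higher in Nod2-/-. The date in the column names is argued against by the design, since each date held as many arrays of either genotype. The lower of the 2 medians within a date was 2.42 on the log2 scale. The set was picked by these same values, so this median is no further evidence. More goblet cells in the Nod2-/- captures, 4-fold as many, are argued against, since 4 of all 6 goblet markers in the table (Ccl9, Spdef, Tff3 and Zg16) lay below the log2 difference of 2 this needs by over 3 standard errors, while a smaller gain stays open. A type 2 response of the epithelium, in which interleukin-13 drives tuft and goblet cell genes, may account for the set. The tuft cell list fixed beforehand had 10 of its 24 genes in the table, all higher. The goblet markers Zg16 and Tff3 were lower on average, however, although in both the arrays of the genotypes overlapped. The list of microbiota-responsive genes also holds Retnlb and the Sprr2a probe sets. The values therefore do not single out a type 2 response. Whether genotype, housing, colony or an infection of one group would bring such a response stays open and was not tested.

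The second pattern is that the listed genes beside Nod2 were lower in Nod2-/-. In a window of Nod2 and 50 protein-coding genes on either side, 12 genes were in the table against a median of 3 over 19627 windows, at percentile 99.8 (98.9 and 99.4 with 25 and 100 genes on either side), and windows overlap, so this is a description. Of the 12, the 5 listed neighbours, Prdx2, Coq9 and Arl2bp were lower, Junb, Ces1c and Cpne2 were higher, and Nlrc5 had probe sets of both directions. Chromosome 8 had the highest share of its genes in the table of all 20 chromosomes compared (5.57%). Alleles carried with the targeted locus from another strain are a candidate explanation, while local effects of the altered locus and shared regulation of neighbours were not tested.

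The third pattern is that fibroblast and matrix genes were higher in Nod2-/-. Stromal tissue carried into the captures could raise them, and the 6 listed smooth muscle, endothelial and myeloid markers were all higher, with a median of 0.47 (0.23 without WT replicate 1), but only 6 of 72 such markers were in the table, no more than its highest background share gives, so this cannot be told apart from a change within the crypt. WT replicate 1 alone could also set the pattern. Without it the mean of the 8 genes was still higher in Nod2-/- by 0.44 with a standard error of 0.26, and the arrays are too few to decide. Sparc averaged 9.64 ± 0.31 in Nod2-/- and 9.13 ± 0.39 in WT, and the laser capture of epithelium was meant to leave such cells out.

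The 6 arrays can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The count at adjusted p under 0.05 was 0 for the real split and at most 0 for the others, as in all 10. For unadjusted p under 0.05 the real count was 1106 and the highest other 2124, and 7 of the 10 splits gave as many. With a fold of at least 1.5 besides, the counts were 146 and 279, again with 7 splits. For probe sets with a log2 difference of at least 0.41 they were 962 and 1497, with 6 splits, and for the authors' p and fold thresholds 287 and 616, with 8 splits. For probe sets at least 4-fold apart they were 12 and 3, with 1 split, the real one. The 12 include several probe sets shared by the Sprr2a genes and several of the gasdermin C family, so they are not 12 separate transcripts. The highest other count at unadjusted p came from WT replicates 1 and 2 with Nod2-/- replicate 1, and the 4 splits that put both arrays of the date of replicate 1 together gave between 1462 and 2124, while the date as a block in limma gave 1418 at unadjusted p under 0.05.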
